A study of Bacillus subtilis with 4 samples.

How the data were processed

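The series compares the transcript levels of Bacillus subtilis W168 wild type with those of a strain with an A-to-C change in the uppS ribosome binding site. Per the labels' protocols, RNA was isolated with a column kit from cultures at an OD600 of 0.4 in LB, treated with DNase, and 20 µg of total RNA were copied to cDNA by indirect labelling with an Alexa Fluor dye, 555 or 647. Each array held the RNA of both strains. On the unswapped arrays the wild type carried Alexa Fluor 555 and the mutant Alexa Fluor 647, and the dye-swapped arrays had the dyes exchanged. The labels give 2 replicates with a dye-swap pair each, 4 arrays in all, whereas the design text speaks of triplicate RNA preparations, and other arrays than these 4 are not analysed here.

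The deposited table holds 1 log2 fold change per gene and array, mutant value divided by wild-type value, and per the labels this direction holds for the swapped arrays too. The log2 scale follows from the values: of the ratios under 4, 100% lay within 0.0005 of a multiple of 0.01, so linear ratios had been rounded before the logarithm was taken, and the lowest ratio recorded is 0.01. Scanner, background correction, normalization and averaging of spots are not given in the sources used here. Array medians were 0 and -0.06 in replicate 1 and 0 and -0.04 in replicate 2 (unswapped first), so the channels had been balanced. The median absolute deviations were 0.45 and 0.46 in replicate 1 and 0.67 and 0.68 in replicate 2. Ratios of exactly 1 were listed 97, 72, 334 and 168 times per array, against 52, 54, 45 and 39 for a ratio of 0.99 and 81, 53, 30 and 42 for a ratio of 1.01, so that the excess was smaller in replicate 1 than in replicate 2, and part of them can stand for spots with no measurement. Low signals cannot be told from strong ones in such a table, and a ratio at the lowest step has no defined size.

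The direction was checked on the values. Across genes, arrays of one dye orientation had Spearman correlations of 0.54 and 0.57 between replicates, and the arrays of a dye-swap pair 0.16 and -0.06, and the part of the ratios that turned with the dyes had an SD over genes of 0.958, against 0.68 for the part shared by all arrays. Neighbouring genes, which often share an operon, were more alike in the part of the ratio with one sign on all arrays (Spearman correlation 0.24 over 2410 neighbour pairs) than in the part that turned with the dyes (0.14; difference 0.106, 95% bootstrap interval 0.048 to 0.165). Runs of at least 3 neighbours that were 1.5-fold higher on all arrays numbered 10, and lower 3, against at most 1 and 2 in 100 shuffles of the gene order, and the genes of opposite sign between the dyes formed 1 run. Of the 10 control probes for foreign RNA, 4 had opposite signs between the dyes on all arrays and 0 had one sign. The ratios were therefore used as the labels state them.

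Of 4116 table entries, the 10 controls were left out, and of 4106 genes 12 lacked a value on an array, which left 4094. The arrays of a dye-swap pair were averaged, and the 2 replicate values were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with no recentring. With 1 residual degree of freedom and a prior of 1.5 degrees, the moderated test has little power: on simulated data with 200 changed genes per run and 20 runs it called 0% of genes changed 2-, 4-, 8- or 16-fold. A rule of size, at least 2-fold the same way on all 4 arrays, was counted beside it and recovered 0.8%, 71.1%, 84.4% and 90.1% of those genes. In 1 replicate of each simulated gene, the 2 arrays deviated by equal and opposite amounts. A gene changed exactly 2-fold could therefore hardly meet the rule, and an unchanged gene could not. An exact sign-flip test of 2 replicates cannot go below a two-sided p of 0.5, and none was run. The gene p-values rest on the spread between 2 RNA pairs and on a prior spread drawn from all genes. Camera p-values at the preset correlation set the members of a list against the other genes. In them genes, and not the 2 replicates, act as the units.

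Gene lists, 36 in number, were written from general knowledge of the organism and tested with camera in limma (preset correlation 0.01, lists with at least 5 measured genes), beside camera with an estimated correlation, fry, and the position of each median among 10000 random lists. On simulated lists of 40 genes drawn at random and shifted by 0.4 log2 units camera called 100% and 0% of the others. The simulated genes varied independently of each other, whereas the lists tested hold genes of shared operons and regulons. The 0% therefore does not give the rate of false calls for those lists. Names were matched directly and then through older names. The gene order came from the reference annotation ASM904v1, which was used only for names and neighbours; 3026 genes matched by symbol and 102 by synonym. The rotation test, which moves all members of a list along this order, was left out where fewer than 80% of a list had a place in it.

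Genes were named by this rule: the uppS locus; the 12 highest and 12 lowest means among genes past the threshold with one sign on all arrays, filled from genes with one sign that did not pass where too few did, which was the case for all 24; up to 4 members with the smallest p in the direction of the median for each list; and sigM, sigW and sigX. The groups, tests, lists, named-gene rule and alternatives were fixed before the data were examined. Alternatives were median centring, each dye orientation alone, each replicate left out, genes with at least 1 array per replicate, a limit of 1 log2 unit on the distance within dye-swap pairs, equal spread of arrays, all 4 arrays with a random block or as independent values, robust limma, other thresholds and sizes, and the other list tests. Exact ratios of 1 as missing, a dye term without a block, random lists matched on the dye-swap distance, and the heat shock list without yflA were added after the data had been seen.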

Results

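Transcript levels of Bacillus subtilis W168, a laboratory strain of a Gram-positive, spore-forming soil bacterium, were compared between the wild type and a mutant with an A-to-C change in the ribosome binding site of uppS. This gene encodes undecaprenyl pyrophosphate synthase, the enzyme that makes the lipid carrier on which cell wall precursors are assembled. RNA of both strains was hybridised to the same 2-colour array, so each array gave a ratio of mutant over wild type for every gene. The 4 arrays held 2 biological replicates, each measured as a dye-swap pair on the same RNA, and the mean of a pair was taken as 1 replicate (n = 2). Cells had been taken from LB cultures at an OD600 of 0.4. A value on all 4 arrays was present for 4094 genes. All errors below are SDs between the 2 replicates, each the mean of a dye-swap pair. They leave out the distance between the 2 arrays of a pair, so a small SD can go with arrays that lie far apart. Spot intensities are not given in the sources used here, so the precision is known only from the spread between replicates and within dye-swap pairs.

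The transcript of the mutated gene itself lay close to equality between the strains. uppS stood at a log2 ratio of 0.065 ± 0.22 (SD, n = 2), with 0.22 in replicate 1 and -0.090 in replicate 2 (adjusted p = 0.87, limma). A ribosome binding site acts on translation, so this transcript level does not check the strain labels. Among its neighbours, dxr, the isoprenoid pathway gene downstream, was lower on all 4 arrays at -0.66 ± 0.17, and frr, the ribosome recycling factor gene upstream, at -0.33 ± 0.12. The protease gene yluC (rasP) stood at -0.17 ± 0.03 and the phospholipid synthesis gene cdsA at -0.28 ± 0.37. The genes proS and polC took both signs among the arrays, with proS at 0.05 ± 0.03. The locus as a list of 7 genes had a median of -0.17, -0.015 in replicate 1 and -0.16 in replicate 2, and did not pass the list test (camera adjusted p = 0.42). None of its members passed the gene test, over all genes or adjusted over the list alone.

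The highest ratios of one sign on all arrays belonged to a small number of gene clusters. In the yxe cluster, yxeP stood 34.7-fold higher in the mutant (log2 5.12 ± 2.78, SD, n = 2), followed by yxeM at 3.94 ± 3.48, yxeQ at 3.84 ± 1.87, yxeN at 3.36 ± 1.43 and yxeR at 2.71 ± 1.18. The sulfate activation genes sat and cysC stood at 4.32 ± 1.37 and 2.66 ± 0.02, and the siroheme synthesis genes ylnD and ylnE at 3.18 ± 0.29 and 2.99 ± 0.78. The remaining genes among the 12 highest were alsD of acetoin synthesis (2.94 ± 0.59), rocB of arginine breakdown (2.85 ± 0.54) and sboA, which encodes the precursor of the antibiotic subtilosin (2.68 ± 0.0018). On single arrays sboA ranged from 2.13 to 3.22.

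The lowest ratios of one sign on all arrays lay largely in prophage and spore coat genes. The PBSX prophage genes xkdX and xkdM stood at -3.75 ± 4.09 and -2.85 ± 1.96 (SD, n = 2), and the phage-related lysin gene xlyB at -3.37 ± 1.80. The SPbeta prophage genes yosF, yopY and yosX stood at -3.04 ± 0.39, -2.89 ± 1.88 and -2.72 ± 3.02, and yqaJ of the skin prophage element at -2.87 ± 2.09. The coat genes cotV and cotY stood at -3.50 ± 0.69 and -2.92 ± 1.61, and cgeA, a gene of spore maturation, at -2.99 ± 0.58. The list closed with yvaX (sdpB) of the cannibalism toxin operon at -3.02 ± 1.56 and gntR, the gluconate repressor gene, at -2.76 ± 1.95. The genes xkdX, xkdM, cgeA, yvaX and yopY reached the lowest ratio recorded, 0.01, on an array of replicate 2. These SDs leave out the distance between the arrays of a dye-swap pair. Averaged over the 2 pairs, it ranged from 0.26 log2 units for xkdX to 4.24 for yvaX. For xkdX both arrays of replicate 2 stood at the lowest ratio recorded, so its small distance does not show precision. For yosF and cgeA, with small SDs, it was 2.61 and 3.98.

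**Figure D1:**
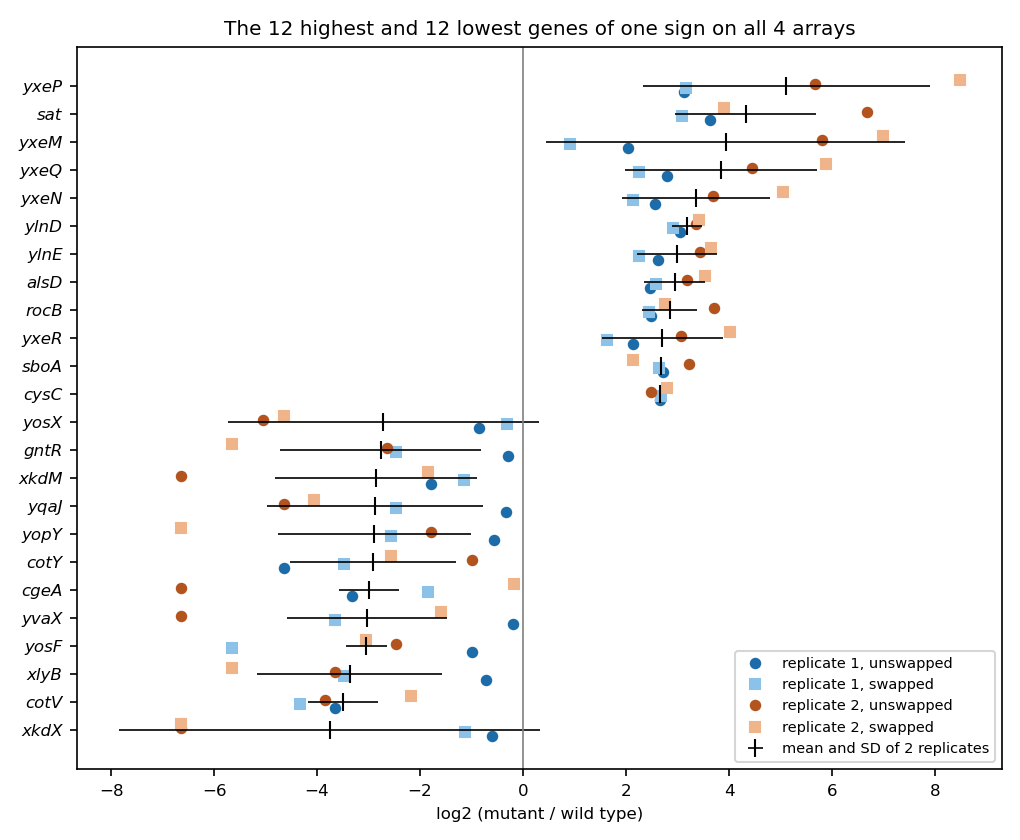
Log2 ratio of mutant over wild type (horizontal axis) for the 12 highest and the 12 lowest genes that had one sign on all 4 arrays; circles are unswapped and squares dye-swapped arrays, blue is replicate 1 and brown replicate 2, and the black bars give the mean and SD of the 2 replicates. The high genes ylnD and cysC lie close together on the arrays, at means of 3.18 and 2.66, whereas yxeP and xkdX spread widely between the replicates, with SDs of 2.78 and 4.09.

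None of these 24 genes passed the test. The limma test called 0 of 4094 genes at an adjusted p under 0.05, the lowest adjusted p being 0.38, and 443 genes lay at an unadjusted p under 0.05 (215 higher and 228 lower, with 205 expected by chance). In simulated data of this design the same test called 0% of genes changed 16-fold, so that a count of 0 does not speak against changes of that size. Among other fits, robust limma and a fit of the 4 arrays with a dye term called 0 genes, the 4 arrays as independent values called 35, and the replicate as a random block called 107. When genes whose dye-swap arrays lay more than 1 log2 unit apart were left out, limma called 29 genes, 24 of them higher and 5 lower. The 24 included ylnD, cysC, alsD, rocB, albA and cysK, and the 5 lower were glpQ, srfAB, srfAC, yknX and yflA.

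A rule of size gave a count that needs no spread from 2 replicates. At least 2-fold higher on each of the 4 arrays were 48 genes, and at least 2-fold lower were 15. Of these 63 genes, 61 lay at an unadjusted p under 0.05, and 27 were among the 29 genes called after the filter on dye-swap distance. That filter kept 36 of the 48 higher and 7 of the 15 lower genes. The rule and both tests use the same 4 values per gene, so this overlap is not independent support. In simulated data the rule recovered 0.8% of genes changed 2-fold, a share kept low by the way the data were simulated, and 71.1% of those changed 4-fold. It took up 0 unchanged genes, but the simulation made this certain. In 1 replicate of each unchanged gene the 2 simulated arrays were exact opposites, so the rule could not be met. The 0 therefore does not show how many of the 63 genes are unchanged. The fixed gene lists held 14 of the 48 higher and 10 of the 15 lower genes. Dye-linked values were frequent: 87 genes were at least 2-fold from equality on every array with opposite signs between the dye orientations, against 1 gene with opposite signs between the replicates.

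**Figure D2:**
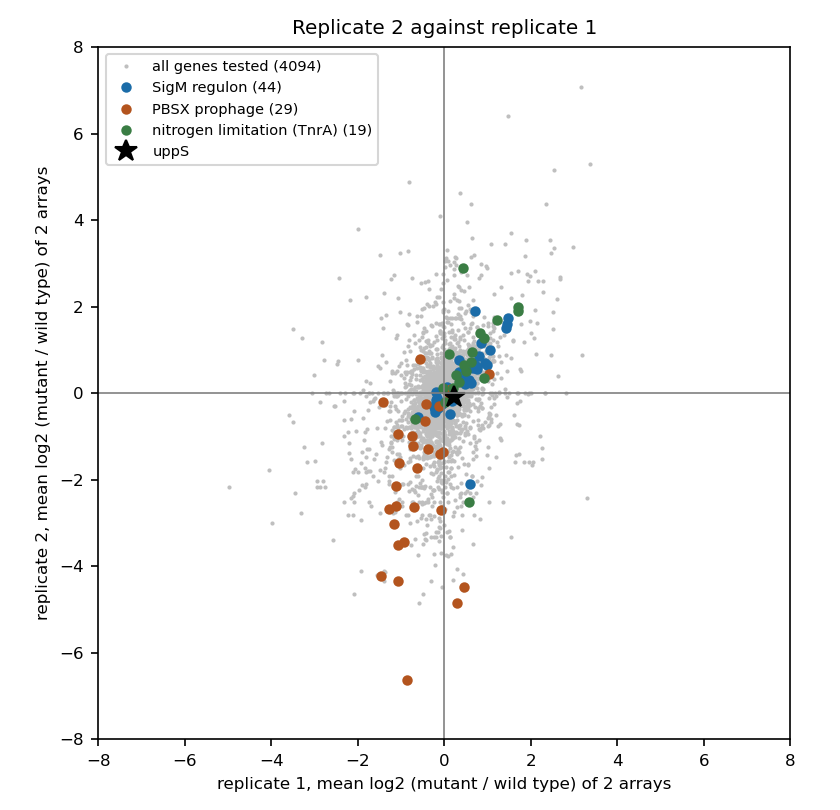
Mean log2 ratio of the dye-swap pair of replicate 2 (vertical axis) against that of replicate 1 (horizontal axis) for the 4094 genes tested (grey), with the 44 SigM, 29 PBSX and 19 TnrA list genes in colour and uppS as a star. Across genes, which are not independent replicates, the replicates had a Pearson correlation of 0.35, and most PBSX genes lie below 0 in both replicates, with list medians of -0.71 and -1.62.

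The regulon of SigM, an alternative sigma factor that responds to cell wall stress, rose in the mutant. Of its 44 measured genes 24 were higher on all 4 arrays and 7 lower, with a median log2 ratio of 0.40, 0.40 in replicate 1 and 0.37 in replicate 2 (n = 2; camera adjusted p = 3.45e-05; adjusted p = 0.97 with an estimated correlation). The members yqjL, ypbG and ywaC (sasA, a synthetase of the alarmone ppGpp) stood at 1.61 ± 0.19, 1.53 ± 0.11 and 1.46 ± 0.06 and met the 2-fold rule, and murG, which makes lipid II, stood at 1.03 ± 0.04. The gene sigM itself stood at 0.66 ± 0.14, higher on all 4 arrays. No member passed the gene test over all genes or adjusted over the list alone, and 23 of the members stood on another list as well.

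The lists of the related sigma factors SigX and SigW gave other values. The SigX list, with many genes of the cell surface, fell by a median of 0.31 (camera adjusted p = 0.035; adjusted p = 0.97 with an estimated correlation), with 12 of 21 genes lower on all arrays and 2 higher. sigX and its anti-sigma factor gene rsiX stood at -0.67 ± 0.01 and -0.64 ± 0.05 (SD, n = 2), lytB, the enhancer of the autolysin amidase, at -0.78 ± 0.21, and dltA of teichoic acid alanylation at -0.56 ± 0.15. The SigW list of 56 genes had a median of 0.07 and a mean of -0.04, with 13 genes higher and 12 lower on all arrays (camera adjusted p = 0.42). At an unadjusted p under 0.05 lay 7 of these genes on the low side and 2 on the high side, and by the 2-fold rule 2 were lower and 0 higher. These 2, yknX and yknZ, stood at -1.56 ± 0.26 and -1.18 ± 0.08 and were named after their values were seen. On the high side, ywoA (bcrC, an undecaprenyl pyrophosphate phosphatase that is also on the SigM list) stood at 0.68 ± 0.02, ybfO at 0.55 ± 0.02 and pbpE at 0.36 ± 0.0041, and sigW at 0.28 ± 0.20. The SigX call was lost on the dye-swapped arrays alone and when list members were moved together along the gene order (adjusted p = 0.24 and 0.16). Of the 21 SigX members, 15 stood on another list as well, among them lytB and dltA.

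Other lists of the cell envelope did not pass the list test. Genes of undecaprenyl phosphate and isoprenoid synthesis had a median of -0.15, -0.059 and -0.21 in the replicates (camera adjusted p = 0.30), with the heptaprenyl diphosphate synthase genes hepT and hepS at -0.78 ± 0.39 and -0.52 ± 0.04 (SD, n = 2) and menH (menG) at -0.57 ± 0.19. Peptidoglycan synthesis, 34 genes, had a median of -0.02 and a mean of 0.10 (camera adjusted p = 0.34, direction up). Of these genes 12 were higher on all arrays and 4 lower, the latter including murD at -0.42 ± 0.01 and murE at -0.50 ± 0.26. Teichoic and teichuronic acid synthesis had a median of -0.21, -0.049 and -0.36 in the replicates (adjusted p = 0.11), with tuaC at -0.45 ± 0.01, and passed on the unswapped arrays alone (median -0.36, adjusted p = 0.0038). The autolysin list had a median of -0.21 (adjusted p = 0.19), with lytC at -0.45 ± 0.16, and passed when genes with dye-swap arrays more than 1 log2 unit apart were left out (median -0.31, adjusted p = 0.031). Medians of -0.32 for the WalRK list, -0.04 for LiaRS and 0.18 for the peptide antibiotic transporters came with camera adjusted p of 0.46, 0.72 and 0.21. The transporter median was 0.20 in replicate 1 and 0.039 in replicate 2. Adjusted over the list alone, 1 WalRK member, ywaC, passed, on the high side against the list median, and 0 members of the other lists of this paragraph did. Fatty acid and phospholipid synthesis had a median of -0.12 (adjusted p = 0.82), with accC at -0.65 ± 0.37. Cell division genes had a median of -0.08 (adjusted p = 0.99), with ftsA at -0.44 ± 0.04. Replicate medians took opposite signs for fatty acid and phospholipid synthesis (0.078 and -0.28), LiaRS (0.13 and -0.20), peptidoglycan synthesis (0.038 and -0.034) and cell division (0.02 and -0.12).

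**Figure D3:**
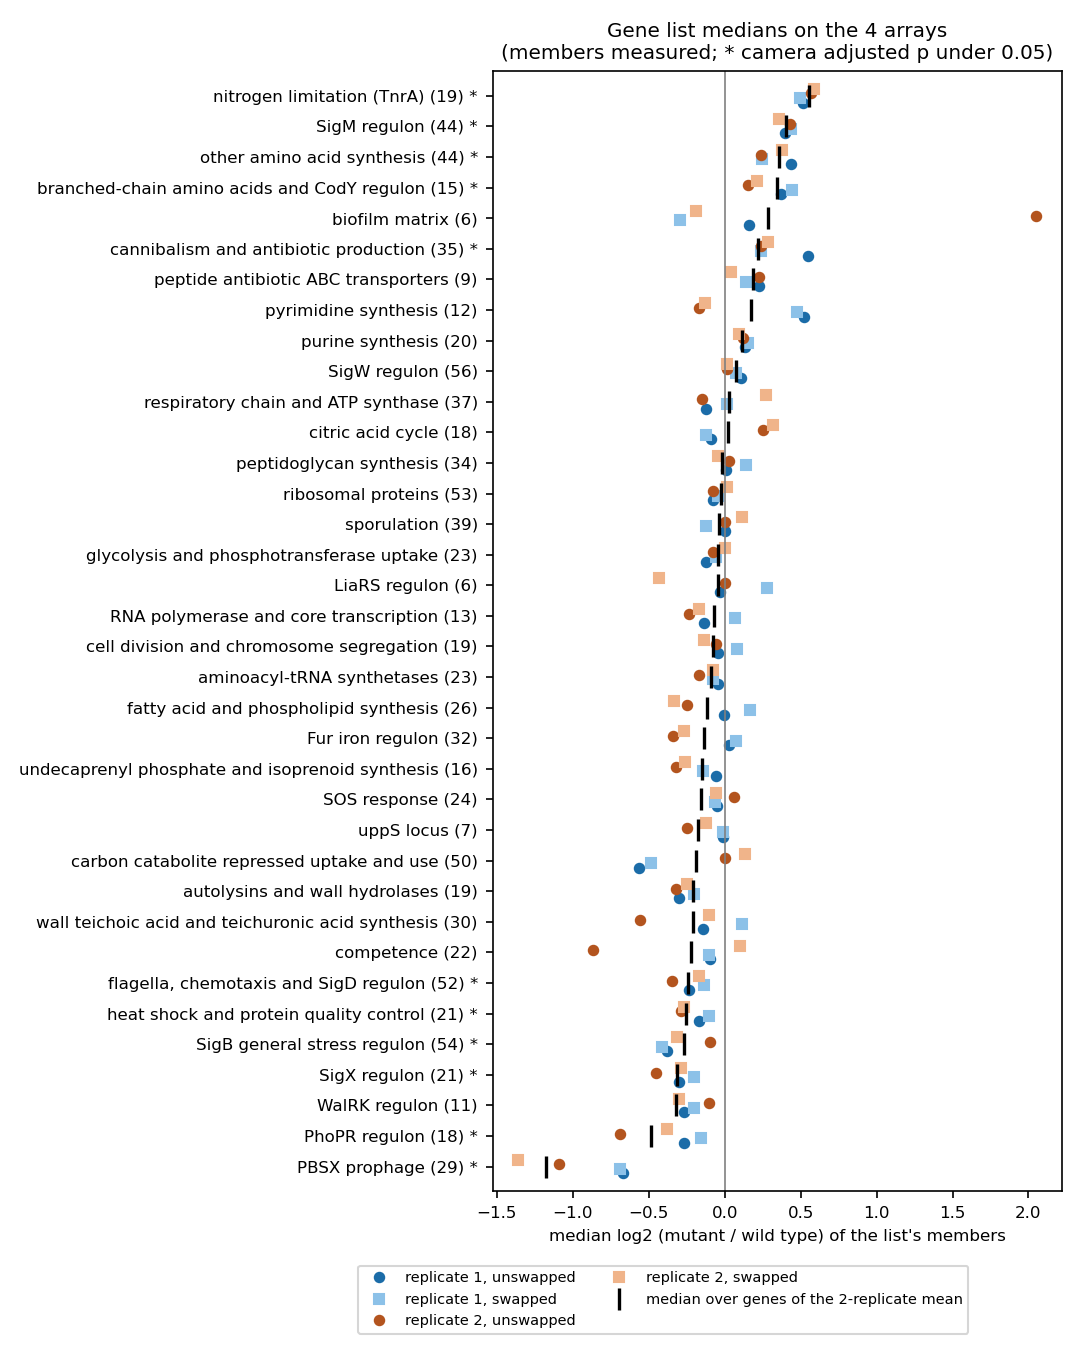
Median log2 ratio of mutant over wild type (horizontal axis) of the members of the 36 fixed gene lists on each array; circles are unswapped and squares dye-swapped arrays, blue is replicate 1 and brown replicate 2, the black bar is the median over genes of the 2-replicate mean, the number of measured members stands in brackets, and an asterisk marks a camera adjusted p under 0.05. The SigM median lies between 0.36 and 0.44 on the 4 arrays and the PBSX median between -1.36 and -0.67.

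Genes of nitrogen supply and amino acid synthesis rose together. The list of TnrA nitrogen limitation genes had a median of 0.56, with 14 of 19 genes higher on all arrays and 1 lower (camera adjusted p = 3.45e-05; adjusted p = 0.97 with an estimated correlation). The urease genes ureC, ureA and ureB stood at 1.85 ± 0.21, 1.80 ± 0.14 and 1.45 ± 0.35 (SD, n = 2), and the nitrate transporter gene nasA at 1.09 ± 0.26. The list of other amino acid synthesis genes had a median of 0.36, with 19 of 44 genes higher on all arrays and 2 lower (camera adjusted p = 3.45e-05; adjusted p = 0.97 with an estimated correlation). Its histidine genes hisG, hisI and hisF stood at 2.0 ± 0.13, 1.41 ± 0.26 and 1.08 ± 0.04, and cysK, a cysteine synthase, at 1.6 ± 0.25. On single arrays hisF ranged from 0.44 to 1.66. Branched-chain amino acid and CodY genes had a median of 0.35, 0.47 in replicate 1 and 0.20 in replicate 2 (camera adjusted p = 0.000457; adjusted p = 0.97 with an estimated correlation), with 6 of 15 higher on all arrays and 0 lower, among them ilvD at 0.49 ± 0.17 and ilvC at 0.42 ± 0.15. No member of the 3 lists passed over all genes, and adjusted over the list alone 2 (ureA and ureC), 0 and 0 did. The branched-chain call was lost on the unswapped arrays alone and on moving the members along the gene order (adjusted p = 0.063 and 0.16).

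The defective prophage PBSX fell in the mutant. Its 29 measured genes had a median log2 ratio of -1.18, a 2.26-fold lower level, -0.71 in replicate 1 and -1.62 in replicate 2, with 19 lower on all 4 arrays and 1 higher (camera adjusted p = 3.93e-05; adjusted p = 0.97 with an estimated correlation). Values of xkdG, xepA, xkdS and xlyA were -1.64 ± 0.73, -1.34 ± 0.39, -1.0 ± 0.09 and -0.88 ± 0.18 (SD, n = 2). No member passed over all genes or adjusted over the list alone. The list of SOS genes, which respond to DNA damage, had a median of -0.16 and did not pass (adjusted p = 0.95), and had replicate medians of opposite sign (-0.05 and 0.055), with ruvB at -0.60 ± 0.34 and uvrB at -0.31 ± 0.02.

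The list of cannibalism and antibiotic production genes split between operons. It rose by a median of 0.22, with 13 of 35 genes higher and 4 lower on all arrays (camera adjusted p = 0.0097; adjusted p = 0.97 with an estimated correlation), and 8 members passed when adjusted over the list alone, against 0 over all genes. These were sboA, albA, albB and albC on the high side and srfAA, srfAB, srfAC and srfAD on the low side. Genes of subtilosin maturation lay high, with albC at 1.85 ± 0.11, albA at 1.80 ± 0.07 and albB at 1.36 ± 0.03 (SD, n = 2). On single arrays albB ranged from 0.57 to 2.11. The surfactin synthetase genes srfAB and srfAC of the same list lay at -2.11 ± 0.19 and -1.78 ± 0.02 and were named after their values were seen. Embedded in that operon is comS, a competence regulator gene, at -2.29 ± 0.18. The competence list as a whole had a median of -0.22 (adjusted p = 0.82), with comS the 1 member that passed when adjusted over the list alone. Sporulation and biofilm matrix lists had medians of -0.04 and 0.28 (adjusted p = 0.94 and 0.42), and the biofilm median came from 6 measured genes and changed sign between the dye orientations (1.0 unswapped, -0.33 swapped). The competence, sporulation and biofilm medians also differed in sign between the replicates (0.0018 and -0.058, -0.09 and 0.023, and -0.018 and 0.89). The cannibalism call was lost on the unswapped arrays alone and on moving members along the gene order (adjusted p = 0.057 and 0.12).

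General stress, motility and phosphate starvation genes fell by smaller medians than the PBSX genes, and the call of the heat shock list rested on 1 member. The SigB general stress list had a median of -0.27, -0.40 in replicate 1 and -0.15 in replicate 2, with 20 of 54 genes lower and 2 higher on all arrays (camera adjusted p = 0.000457; adjusted p = 0.97 with an estimated correlation), and its members yjgD, gsiB and ydaE stood at -1.11 ± 0.07, -0.75 ± 0.13 and -0.73 ± 0.02 (SD, n = 2). On single arrays yjgD ranged from -2.18 to -0.14. The flagella, chemotaxis and SigD list had a median of -0.24, with 28 of 52 lower and 2 higher on all arrays (camera adjusted p = 0.00499; adjusted p = 0.97 with an estimated correlation), with fliE at -0.49 ± 0.21 and flhA at -0.45 ± 0.16. The heat shock list had a median of -0.26, with 14 of 21 lower and 2 higher (camera adjusted p = 0.046; adjusted p = 0.97 with an estimated correlation), with groES at -0.59 ± 0.01, groEL at -0.44 ± 0.08 and the amino acid transporter gene yflA at -1.28 ± 0.01. Without yflA the heat shock list did not pass, at a median of -0.22 with 13 of 20 lower and 2 higher (camera adjusted p = 0.11). The PhoPR list had a median of -0.48, -0.14 in replicate 1 and -0.69 in replicate 2, with 7 of 18 lower and 1 higher (camera adjusted p = 0.035; adjusted p = 0.97 with an estimated correlation). Its member glpQ, a glycerophosphodiester phosphodiesterase gene, stood at -1.77 ± 0.06 and was the 1 gene of these 4 lists to pass when adjusted over the list alone. The flagella, heat shock and PhoPR calls were lost on the dye-swapped arrays alone (adjusted p = 0.35, 0.24 and 0.50), and the heat shock call also after centring each array (adjusted p = 0.053).

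Lists of central metabolism and of the growth machinery did not pass the list test. Ribosomal proteins, 53 genes, had a median of -0.02 (camera adjusted p = 0.95), RNA polymerase and core transcription -0.07 (0.60) and aminoacyl-tRNA synthetases -0.09 (0.30). Glycolysis and phosphotransferase genes had a median of -0.04 and a mean of 0.11 (0.92), with the lactate permease gene lctP at -0.79 ± 0.00092 (SD, n = 2), and the citric acid cycle a median of 0.02 (0.50), with citZ at 0.49 ± 0.15. The respiratory list had a median of 0.03 (0.30), yet its nitrate respiration genes narK and fnr stood at 1.27 ± 0.22 and 1.10 ± 0.17, and narH at 0.70 ± 0.02. Purine synthesis had a median of 0.11 (0.34), with purN at 0.66 ± 0.15. Pyrimidine synthesis had a median of 0.17 (0.42) and parted the replicates, at 0.52 and -0.13, with pyrF at 0.56 ± 0.90. Carbon catabolite repressed genes had a median of -0.19 (0.36), -0.49 and 0.06 in the replicates, and the Fur iron regulon -0.14 (0.50), 0.073 and -0.33 in the replicates, with yclO at -0.60 ± 0.21. Replicate medians also took opposite signs for the citric acid cycle (-0.11 and 0.20), the respiratory list (-0.052 and 0.12) and RNA polymerase (0.035 and -0.18). The respiratory list passed on the dye-swapped arrays alone (median 0.12, adjusted p = 0.023), and the catabolite list against random lists matched on dye-swap distance (adjusted p = 0.041). Adjusted over the list alone, the acetolactate synthase gene alsS of the glycolysis list passed, at 2.44 ± 0.22, and 0 members of the other lists of this paragraph did.

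The list calls have limits set by the design. At the preset correlation, camera takes genes and not replicates as its units, so its small p-values do not show replication. With an estimated correlation, camera tests on 1 residual degree of freedom, and 0 of the 11 lists passed. The flagella list lost its call there although its estimated correlation of -0.014 lay below the preset 0.01. The loss by this test therefore does not show that correlation between genes made the calls. By fry, which tests whether a list's genes move one way on balance, 0 passed in direction (adjusted p = 0.54 for each) or as mixed changes. When list members were moved together along the gene order, 6 lists passed, namely SigM, TnrA, other amino acid synthesis, PBSX, SigB and PhoPR. These moves keep the spacing of the members but can carry them across operon borders.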

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

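The check for single arrays far from the other 3 was planned for all genes and lists named, and the genes discussed here were picked out by it and not otherwise. It compares the distance of the highest or lowest array to its neighbour with the whole range of the 4 arrays. Chance flags about 1 in 20 such groups, and 10 were found among 164 genes and 36 lists, so no pattern among them stands out.

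On the dye-swapped array of replicate 2, pssA stood lower than on the other 3 arrays at -0.42, and rplC, rpoC and yvcS stood higher at 0.18, 0.057 and 0.41. On the unswapped array of the same replicate, valS stood at -1.40, xkdM at -6.64, which is the lowest ratio the table records, and yqjL at 1.96. In replicate 1, dxr stood nearer to 0 on the dye-swapped array, at -0.34. The median of the cannibalism and antibiotic list stood apart on the unswapped array of replicate 1, at 0.55, and that of the SOS list on the unswapped array of replicate 2, at 0.063. No explanation was tested for these values.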

How the results depend on the processing

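The exact ratios of 1 as missing, the dye term without a block, the matched random lists and the heat shock list without yflA were chosen only after the data were seen. The count of 0 genes past the threshold was kept under centring, each dye orientation alone, at least 1 array per replicate, exact ratios of 1 as missing, equal spread, robust limma, the dye term, and the thresholds 0.01, 0.1 and 0.05 with 2-fold. It moved to 29 with the limit on dye-swap distance (2503 genes left), to 107 with the replicate as a random block, whose consensus correlation was negative at -0.28, and to 35 with independent arrays. At an unadjusted p under 0.05, the random block gave 935 genes, independent arrays 725 and the dye term 745, against 443. The fit with a dye term and a random block was not run, since its correlation could not be estimated. By the 2-fold rule on the unswapped arrays alone, 166 genes were higher and 140 lower, and on the dye-swapped arrays 161 and 255, since only 2 arrays had to meet it; leaving out a replicate gave 81 to 100 higher and 69 to 109 lower for the same reason. The limit on dye-swap distance left 7 lower genes, and exact ratios of 1 as missing gave 34, since fewer arrays then had to meet the rule. At 1.5-fold, 107 and 48 genes met it, and at 3-fold 19 and 4. uppS ranged from -0.090 to 0.22 with a replicate left out, and stayed between 0.065 and 0.091 in the other fits. Lists past the test numbered 11, and 0 with an estimated correlation, 0 by fry, 6 by rotation, and 8 to 12 otherwise. Sign changes were seen for polC (0.022 after centring), for dppE (-0.21), polC (0.014), proS (-0.030), spoIVB (2.0), spoVD (0.44) and ywjD (1.76) on unswapped arrays, and for acuA (0.53), slr (-0.71), tasA (-1.24), yqxM (-0.43), yvqC (0.017) and yxeA (-4.85) on dye-swapped arrays; the cause was not tested. Each ratio already pairs the strains on 1 array, so that the test against 0 is the paired analysis, and no further block of the strains could be fitted. Signal over background is unknown here, so weak spots could not be left out.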

Other observations

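The 6 lists and the runs of neighbours described first, and the tests of dye bias and of growth stage, were chosen only after values of their genes had been seen, so their p-values are not independent evidence. Genes of sulfate assimilation and of the CymR regulon, which serve sulfur supply, had a median of 0.83, with 21 of 41 higher on all arrays and 1 lower (camera adjusted p = 2.9e-08 over the added lists; adjusted p = 0.31 with an estimated correlation), and 15 of them met the 2-fold rule. Beyond the genes named above, cysP stood at 1.69 ± 0.12 (SD, n = 2) and the cystine transporter gene yhcL (tcyP) at 2.27 ± 0.79. Genes of arginine and ornithine use had a median of 2.34, with 7 of 8 higher on all arrays, among them rocD at 2.25 ± 0.46, rocE at 2.34 ± 0.52 and rocF at 2.33 ± 0.58. The oxygen limitation list had a median of 0.38, with 19 of 34 higher and 2 lower, which includes the sbo-alb operon and arfM at 1.47 ± 0.26. Riboflavin genes had a median of 1.22, with 6 of 6 higher and ribE at 1.75 ± 0.13, and histidine synthesis 1.59, with 7 of 8 higher. All of these passed camera, and none with an estimated correlation (adjusted p = 0.31 for each). By fry, the sulfate and oxygen limitation lists passed in direction (adjusted p = 0.014 for each), and the arginine, riboflavin and histidine lists did not (adjusted p = 0.12, 0.12 and 0.11). Without the genes already singled out, the sulfate list missed camera (adjusted p = 0.056). The oxygen limitation (26 genes, median 0.25), histidine (6, 1.59) and SPbeta prophage (173, -0.51) lists still passed camera (adjusted p = 0.00018, 8.3e-06 and 1.1e-05). By fry their adjusted p was 0.032, 0.11 and 0.012, and with an estimated correlation 0.31 for each.

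Prophage SPbeta lay lower, with a median of -0.51 over 178 genes, 27 lower and 13 higher on all arrays (camera adjusted p = 1.41e-05; adjusted p = 0.31 with an estimated correlation; adjusted p = 0.012 by fry). Its array medians were -0.20 and -0.39 in replicate 1 and 0 and -0.68 in replicate 2 (unswapped first). The median distance within dye-swap pairs was 1.85 log2 units, which describes single genes and not the precision of the list median. Random lists matched on this distance, which do not keep neighbours together, had a median of -0.11, and the list lay at their percentile 0. The bacteriocin-region genes bhlA and sunA of this prophage stood at 2.31 ± 0.04 and 1.88 ± 0.37 (SD, n = 2). Runs of neighbours that were 1.5-fold from equality on all arrays and are on none of the lists were mntA to mntD of manganese uptake, with a mean of 0.95, yhcA to yhcD, with a mean of 0.98, and sigY with yxlC, yxlD, yxlE and yxlF, with a mean of -0.84.

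The first pattern weighed is the higher SigM regulon. Shared operons alone are argued against, since a share of 0.00032 of the gene-order rotations gave a median as far from that of all genes, the smallest share they can give. The rotations keep the spacing of the members and not operon borders, so this holds only as far as spacing stands for operons. A wide distance within dye-swap pairs is argued against as the cause by a median at percentile 100 of the matched random lists, and dye bias by a lowest array median of 0.36. Weak signal itself could not be tested, since spot intensities are not known. A difference between the cultures that recurred in both replicates stays open, as does an effect of the uppS change, which was not tested apart from the strain itself.

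The next pattern is the lower PBSX prophage. The list lay at percentile 0 of lists matched on dye-swap distance, which argues against a wide distance within pairs as the whole cause. Weak signal itself could not be tested, since spot intensities are not known. The distance does not stand for it: xkdX had a distance of 0.26 with both replicate 2 arrays at the lowest ratio recorded. The highest array median was -0.67, which argues against dye bias as the whole cause. A share of 0.00543 of the rotations gave as extreme a median. This speaks against shared operons only as far as spacing stands for operons, since rotated members can cross operon borders. The size is less certain than the direction, since the median was -0.71 in replicate 1 and -1.62 in replicate 2. A different share of induced cells in the cultures stays open and was not tested.

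The last pattern is the higher sulfate and CymR genes. Dye bias as the whole cause is argued against by array medians of all 41 members of 1.25 and 1.51 unswapped and 0.77 and 0.97 dye-swapped, since a dye effect turns with the swap, but in the 25 members not singled out it cannot be told apart, at 0.61 and 0.19 unswapped and -0.029 and 0.043 dye-swapped. A later growth stage of the mutant culture cannot be told apart, since no test run here separated it. The SigB list had a median of -0.27 (-0.40 in replicate 1 and -0.15 in replicate 2). Its call was lost with an estimated correlation (adjusted p = 0.97) and by fry (adjusted p = 0.54). All 11 calls of fixed lists were lost in these 2 tests, so the losses do not bear on growth stage. The acetoin synthesis genes alsS and alsD, known to be raised towards the end of growth, stood at 2.44 and 2.94, and the oxygen limitation list at a median of 0.38. The surfactin genes srfAB and srfAC and the competence gene comS lay lower, at -2.11, -1.78 and -2.29. How growth stage acts on them was not tested. Whether the list stands out beyond the genes that prompted it cannot be told apart from selection: these 25 members lay at percentile 99.1 of matched lists, but had a median of 0.19 and missed the list test (camera adjusted p = 0.056). A difference in medium or in sulfur supply between cultures remains a possible explanation that was not tested.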
